A study of Caenorhabditis remanei with 48 samples.

How the data were processed

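The samples were first-stage larvae of *Caenorhabditis remanei* from an ancestral population and from a control-selected and a heat-selected population derived from it. Parents lived at 20 or 30 °C, and their offspring were incubated for 20 h at 20 or 30 °C. Per the labels' protocols, bleached embryos hatched in buffer without food, passed a 20-micron filter and were pooled at about 100000 individuals per replicate before polyadenylated RNA was sequenced. The labels give 6 batches: A and B for the ancestor, C and D for the control-selected and E and F for the heat-selected population. All libraries of heated parents are in A, C and E. The labels do not say whether the replicates were separate cultures, nor whether the libraries were stranded.

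The values are read counts per gene model, as deposited by the authors in 1 file per library, made by alignment with GSNAP version 2013-03-31 and counting with HTSeq (version not given) per the submitters' processing notes. The genome build is not given, and the identifiers carry the strain name PX356. Each file lists 24723 gene models and 5 categories of reads outside the counts. The values were checked to be whole numbers with totals that differ between libraries. HTSeq sets reads that fall on overlapping models aside as ambiguous (1.98 to 5.41% of a library).

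Reads in genes made up 31.3 to 72.8% of a library, reads outside genes 8.03 to 47.1%, reads not aligned 9.77 to 37.5% and reads aligned more than once 1.8 to 6.12%. Scaling factors by the trimmed mean of M values (TMM) ran from 0.72 to 1.52. The first 4 principal components of log2 counts per library size held 31.5, 17.1, 7.46 and 4.89% of the variance. Within each population (16 libraries) the first component followed the TMM factor (Pearson r = −0.97, −0.92 and −0.96 in ancestor, control-selected and heat-selected; Spearman −0.96, −0.96 and −0.92). Permutation p-values were 1e-05, 2e-05 and 1e-05, and 3e-05, 4e-05 and 3e-05 after Benjamini-Hochberg adjustment over 6 relations. It also followed the percent of reads not aligned (r = 0.86, 0.73 and 0.79; Spearman 0.85, 0.76 and 0.79; permutation p = 3e-05, 0.002 and 0.00034, adjusted 4.5e-05, 0.002 and 0.00041). Without the 2 libraries farthest from the median of the measure, r was −0.96, −0.9 and −0.96 for the TMM factor and 0.84, 0.68 and 0.76 for reads not aligned.

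Genes were tested with edgeR (version 4.0.16, R 4.3.3) on the deposited counts, with TMM scaling and the filter of filterByExpr at a minimum count of 10, which kept 13460 genes. One quasi-likelihood fit held all 48 libraries, 12 groups and the batch given in the labels. The differences between populations had no batch term, since batches are nested in populations. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, the adjustment covering the 13460 genes of a comparison. There were 21 comparisons: the larval temperature effect with unheated parents in each population and its differences between populations, the population differences at each larval temperature with unheated parents, the parental effect averaged over both larval temperatures in each population and its differences between populations, and the interaction of parental and larval temperature in each population. Fold changes are on the log2 scale with the standard error of the fit. CPM are counts scaled by library size and TMM factor, given as mean ± SD over the libraries of a group.

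The comparisons, the threshold and most alternatives were chosen before the data were examined. The planned lists of genes by function and their set tests could not be run, since the identifiers pair with locus tags but not with gene names. Of the gene models, 15248 matched a locus tag of another assembly (10462 of those tested), and 11999 lie on numbered linkage groups. The rule for this case, set in advance, names in each comparison the 2 identifiers that rose and the 2 that fell most among called genes with a mean log2 CPM of at least 1.

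Correlations of fold changes are Pearson's r across genes, with Spearman's value beside it. Their errors come from a jackknife that leaves out 1 library at a time. They set populations that share no library against each other. Slopes are orthogonal regressions. Shares of genes have exact (Clopper-Pearson) 95% binomial intervals. Regroupings of the libraries (up to 100 per comparison) used limma-voom on the compared libraries alone, so the count of the real grouping differs from that of limma-voom on all 48.

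Alternatives set in advance were DESeq2's size factors, scaling to total counts, no filter, a minimum count of 50, DESeq2 (1.42.0) and limma-voom (limma 3.58.1) as tests, no batch term, a fit within the population, single batches, a replicate block, 3 treatments of batch for the population differences, a threshold on fold change and leaving out each library. Added after the data were seen were 1 surrogate variable (sva 3.50.0), ancestor batches taken from the replicate number, omission of 4 libraries with over 35% of reads outside genes, omission of 2 ancestor libraries, thinning to the lowest total, correlations over called genes, and consecutive replicates summed in pairs.

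The fit was tested on simulated data, in which 200 of 13460 genes were changed. A log2 change of 1 was recovered for 57% of the genes in the larval effect of the ancestor, 58% in a population difference at 20 °C, 48% in the parental effect of the ancestor, 26% in a difference of larval effects, 11% in a difference of parental effects and 4% in the interaction of parental and larval temperature. At a log2 change of 2 the shares were 91, 92, 82, 63, 56 and 54%. All recovered genes had the right direction, and between 2 and 11 unchanged genes were called. The simulated libraries were independent draws, with no batch difference and no likeness between consecutive replicates. These shares and false calls therefore do not cover such structure in the real libraries.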

Results

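Gene counts came from polyadenylated RNA of pooled first-stage (L1) larvae of *Caenorhabditis remanei*, an outcrossing relative of *C. elegans*. The 48 libraries fell into 12 groups: 3 populations (an ancestor, a control-selected and a heat-selected population, both derived from the ancestor), 2 parental temperatures (20 and 30 °C) and 2 larval temperatures (20 and 30 °C). Each population had 6 libraries per larval temperature when the parents lived at 20 °C and 2 when they lived at 30 °C. Counts in genes ranged from 1986767 to 12717722 per library, with medians of 6173990 in the ancestor, 4508711 in the control-selected and 3254665.5 in the heat-selected population. Between 14388 and 18584 of the 24723 gene models had a count in a library, and 13460 were tested. The files pair the identifiers with no gene names, so genes appear here by identifier and nothing is said of their function.

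The heat-induced gene CRE18322 shows how the libraries were structured. In heat-selected larvae at 30 °C it stood at 13200 and 11000 CPM (counts scaled by library size) in replicates 1 and 2, at 16800 and 18400 in replicates 3 and 4, and at 1990 and 1790 in replicates 5 and 6. CRE_PX356_1986 in control-selected larvae at 30 °C gave 66.7 and 81.8, then 11800 and 10700, then 1180 and 982 CPM. At 30 °C replicates 3 to 6 lay closer within than between these consecutive pairs in all 3 populations with parents at 20 °C. At 20 °C they did so in none. A random pairing would meet this condition in at most 33.3% of groups. The p-values below count each library as a replicate and measure only the spread between these samples. Each count of genes is therefore followed by the count with consecutive replicates summed in pairs, a test added after the data were seen, which leaves 3 values in the groups of 6 and 1 in the groups of 2. The lone values are assumed to vary like the other groups.

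The first question was how larvae of unheated parents respond to 30 °C. Incubation lasted 20 h at both temperatures and time since hatching was not compared, so the responses include any difference in age or time without food. In ancestor larvae CRE_PX356_1986 averaged 6670 ± 5890 CPM (SD, n = 6) at 30 °C and 22.5 ± 23.5 at 20 °C, a fitted log2 fold change of 8.19 ± 1.44 (SE). CRE26773, on linkage group 4, rose from 0.181 ± 0.164 to 51.3 ± 24.3 CPM (log2 fold change 7.81 ± 0.93). All 6 libraries at 30 °C, from 23.3 CPM upward, exceeded the highest at 20 °C, 0.435 CPM. CRE19026 changed from 19.7 ± 20 to 1 ± 0.877 CPM (−5.06 ± 0.32) and CRE13477 from 50.3 ± 9.08 to 2.38 ± 0.629 CPM (−4.24 ± 0.22), each lower in all 6 libraries at 30 °C than in any at 20 °C. Adjusted p-values of these 4 genes were 2.5e-05, 3.3e-08, 1.4e-15 and 8.5e-19 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In all, 5255 of the 13460 genes passed, 2851 higher and 2404 lower at 30 °C, and 2623 of them changed by at least 1 on the log2 scale. Scaled to total counts alone, 1701 of 5074 calls were higher, as the median gene then shifted by −0.29 on the log2 scale. Summed in pairs, 2293 genes passed, all among the 5255. The count was 2893 in batch A and 2958 in batch B alone.

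Control-selected larvae raised CRE_PX356_1986 from 19.4 ± 25.9 to 4120 ± 5520 CPM (log2 fold change 6.97 ± 1.72) and CRE18322 from 26.9 ± 24.6 to 3840 ± 4250 CPM (6.75 ± 0.97; SD of CPM and SE of log2, n = 6). CRE19026 again fell, from 23.8 ± 5.4 to 0.488 ± 0.358 CPM (−5.57 ± 0.35), and CRE24133 from 365 ± 185 to 15.1 ± 13.9 CPM (−4.95 ± 0.44). These genes were higher, or lower, in all 6 libraries at 30 °C than in any at 20 °C. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment their adjusted p-values were 0.0025, 1.9e-06, 9.7e-16 and 3.4e-11. The test called 3153 genes, 1646 higher and 1507 lower at 30 °C. With pairs as replicates 723 genes were called, 722 of them among the 3153, and CRE_PX356_1986 was not among them. Batch C alone gave 357 genes and batch D alone 3250.

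In heat-selected larvae the largest rises under the naming rule were those of CRE_PX356_198 and CRE21296. CRE_PX356_198 went from 0.244 ± 0.598 to 33.9 ± 35.9 CPM (log2 fold change 6.87 ± 0.70) and CRE21296 from 4.64 ± 10.7 to 250 ± 122 CPM (5.82 ± 0.79). Both lie in the same stretch of linkage group 2, and both were higher in all 6 libraries at 30 °C than in any at 20 °C (SD and SE as before, n = 6). CRE24278 stood at 20.4 ± 17 CPM at 20 °C and 0.0992 ± 0.16 at 30 °C (−7.45 ± 0.66), and CRE19026 fell from 9.57 ± 6.78 to 0.156 ± 0.261 CPM (−5.81 ± 0.48). CRE24278 was low at 20 °C in replicates 1 and 2 as well, at 1.49 and 0 CPM. Adjusted p-values were 1.6e-09, 5.2e-07, 3.6e-11 and 7e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 3000 genes called, 1439 were higher and 1561 lower at 30 °C, and scaling to total counts gave 821 higher of 2799. With pairs summed 683 genes passed, all among the 3000; batch E alone gave 759 and batch F alone 2235.

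**Figure D1:**
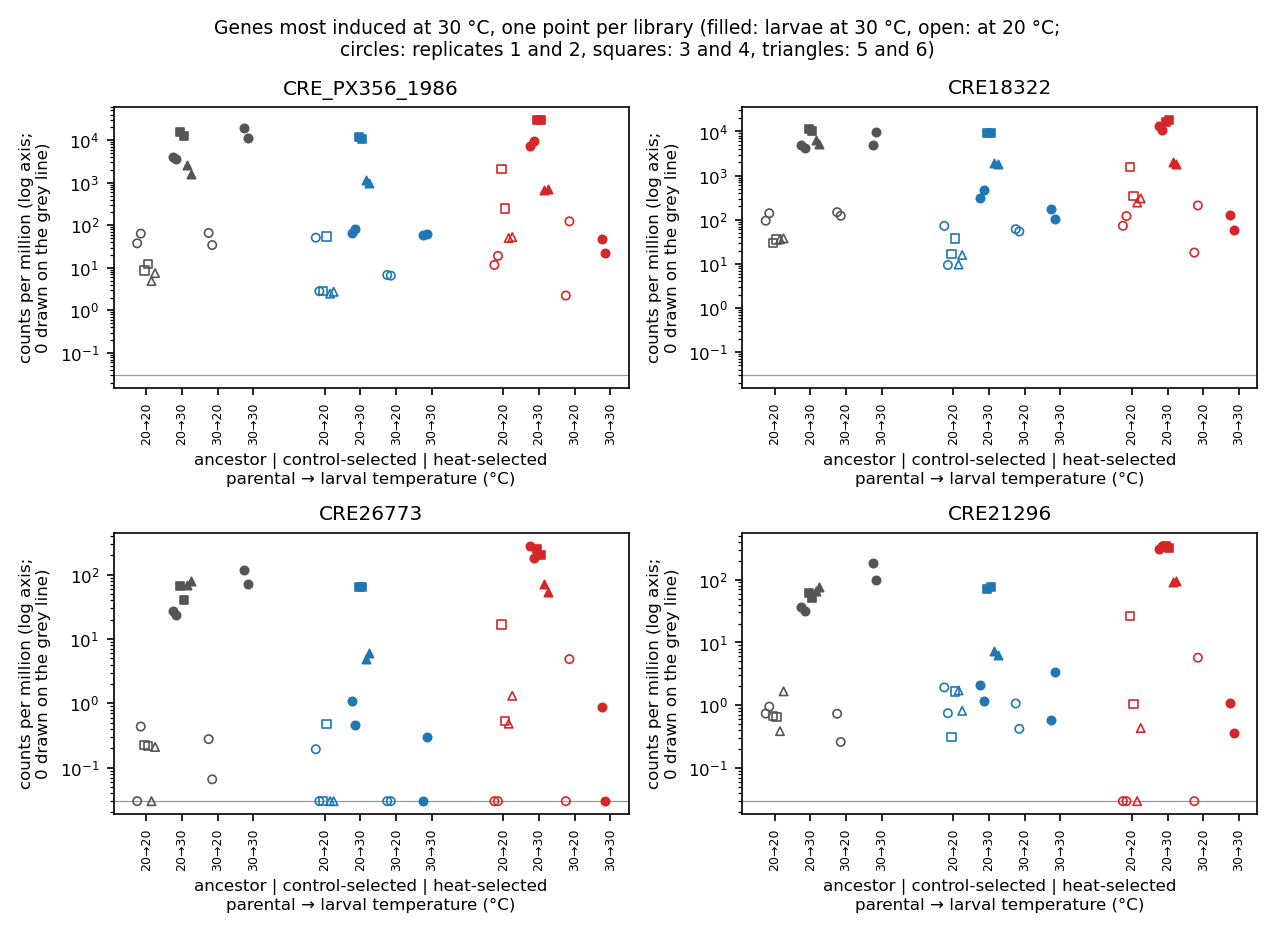
CPM (log axis) of 4 genes named for the response to 30 °C, with 1 point per library in each population and each combination of parental and larval temperature. CRE18322 reached 7050 ± 2950 CPM in ancestor larvae of unheated parents at 30 °C and 92.4 ± 47.3 in heat-selected larvae at 30 °C whose parents had lived at 30 °C.

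The 3 populations moved many of the same genes. CRE19026 fell in each population, and 1445 genes were called in all 3, of which 1440 had the same sign: 742 higher and 698 lower at 30 °C. The heat-selected population and the ancestor, which share no library, both raised 1114 genes and lowered 1095, against 304.8 and 278.8 for independent lists of those sizes. The control-selected population and the ancestor shared 1056 raised and 979 lowered genes (348.6 and 269.2 if independent), and the derived populations shared 880 and 887 (176 and 174.8). Across all tested genes, which are not independent replicates, log2 fold changes correlated with r = 0.713 (jackknife SE 0.097) between ancestor and heat-selected, 0.65 (0.112) between ancestor and control-selected and 0.692 (0.054) between the derived populations. Spearman's values were 0.7, 0.631 and 0.703. Among genes called in the remaining population, the orthogonal slope was 0.87 ± 0.11 for heat-selected on ancestor and 0.84 ± 0.12 for control-selected on ancestor. It was 1.07 ± 0.22 for heat-selected on control-selected, and no slope differed from 1 by more than 2 SE. The slopes differed between fits of single batches: for heat-selected on ancestor, control-selected on ancestor and heat-selected on control-selected they were 1.45, 0.78 and 2.09 in batches A, C and E alone and 0.73, 0.89 and 0.83 in batches B, D and F alone. These slopes have no error and cover the genes called in their own fits, so a dependence on batch was not tested.

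**Figure D2:**
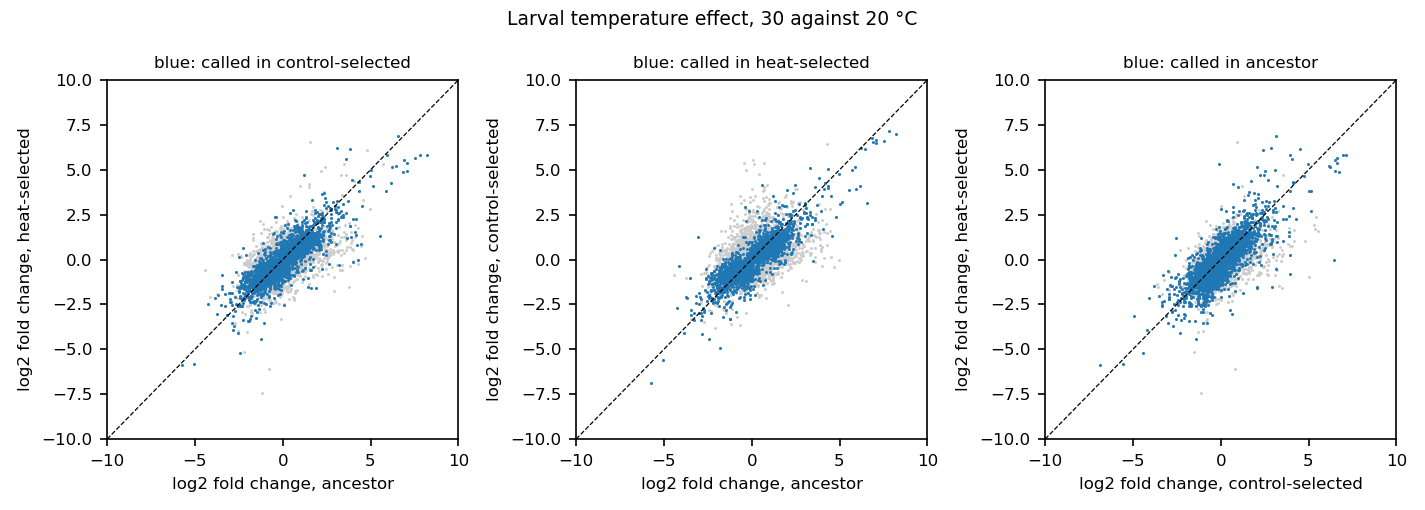
Log2 fold change at 30 against 20 °C of each tested gene in pairs of populations, with the genes called in the remaining population in blue and the line of equal change dashed. Points follow the dashed line, with r between 0.65 and 0.713 over all tested genes.

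Whether the larval response differed between populations was tested as the difference between their responses. Each selection regime is a single population with its own batches, so such a difference cannot be assigned to selection. CRE11034 went from 5.8 ± 4.84 to 153 ± 134 CPM in the ancestor and from 18.5 ± 11.1 to 41.1 ± 10.1 in heat-selected larvae (SD, n = 6), a difference in log2 response of −4.21 ± 0.57 (SE). CRE23514 went from 2.02 ± 1.42 to 11.9 ± 12.7 CPM in the ancestor and from 10.9 ± 7.82 to 7.47 ± 4.68 in heat-selected larvae (−3.51 ± 0.76), a call lost with ancestor batches taken from the replicate number. CRE05046 was lower at 30 °C in the ancestor (14.2 ± 3.23 to 2.99 ± 0.945 CPM) but not in heat-selected larvae (7.72 ± 7.45 to 10.9 ± 5.2), a difference of 2.89 ± 0.37. CRE01098 differed by 3.13 ± 0.68, with 82.6 ± 75.9 CPM in heat-selected and 11.6 ± 5.08 in ancestor larvae at 30 °C. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 61 genes differed (17 with a higher response in heat-selected larvae, 44 lower), with adjusted p-values of 1.6e-05, 0.016, 7.3e-06 and 0.016 for these genes. The fitted responses had opposite signs in 42 of the 61, and in 15 they had the same sign but were smaller in heat-selected larvae. Most of these signs rest on a response that was not called in 1 population. Only 14 of the 61 were called for larval temperature in both populations, 6 of them with opposite signs. Another 37 were called in the ancestor alone and 10 in heat-selected larvae alone. With pairs summed edgeR called 0 genes (403 at an unadjusted p under 0.05), while DESeq2 and limma-voom on the single libraries called 106 and 71.

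Control-selected larvae differed from the ancestor in the response of CRE29510, at 127 ± 187 CPM at 30 °C against 3.91 ± 3.14 in the ancestor (SD, n = 6), a difference in log2 response of 5.43 ± 0.97 (SE). CRE26693 reached 81.1 ± 117 against 4.21 ± 3.15 CPM (5.18 ± 0.85). In both genes the high values came from control-selected replicates 5 and 6, at 247 and 456 CPM for CRE29510. CRE24133 fell further in control-selected larvae (−3.17 ± 0.56), a call lost with ancestor batches taken from the replicate number. CRE_PX356_6307 had a fitted difference of −3.52 ± 0.90, but its ancestor means were alike (65.6 ± 68.3 CPM at 20 °C and 62.8 ± 85.5 at 30 °C). Its call was lost without ancestor replicates 5 and 6 at 30 °C, which are labelled batch A and stood at 28.9 and 29.8 CPM against 0.718 and 0.782 in the other batch A libraries at 30 °C. These were among 117 genes, 58 with a higher and 59 with a lower response, and their adjusted p-values were 0.0039, 0.0013, 0.0039 and 0.042 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Scaled to total counts, 90 of 142 were higher. With ancestor batches taken from the replicate number 44 were higher and 4 lower, and with a replicate block 12 and 2, so the even split holds in neither. With pairs summed edgeR called 0 genes (780 at an unadjusted p under 0.05), against 294 by DESeq2 and 118 by limma-voom on single libraries.

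Between the derived populations, CRE02205 rose at 30 °C in control-selected larvae (1.56 ± 0.517 to 6.58 ± 1.89 CPM) and stood at 5.52 ± 3.21 and 1.6 ± 1.48 CPM in heat-selected larvae at 20 and 30 °C (SD, n = 6), a difference of −3.67 ± 0.52 (SE). CRE30718 differed by −3.36 ± 0.70. CRE15096 dropped from 22.2 ± 9.07 to 2.67 ± 0.637 CPM in control-selected larvae and stood at 9.19 ± 5.77 and 5.9 ± 4.08 CPM in heat-selected larvae, a difference of 2.34 ± 0.48, and CRE05046 differed by 1.82 ± 0.36. Of 30 genes called, 6 had a higher and 24 a lower response in heat-selected larvae, with adjusted p-values of 7.4e-05, 0.016, 0.015 and 0.0098 for these genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Scaling to total counts gave 2 higher of 51, and 1 surrogate variable 166 higher and 110 lower, so the majority direction depends on the fit. Summed in pairs, edgeR called 0 genes (347 at an unadjusted p under 0.05), while DESeq2 called 79 and limma-voom 27 on single libraries.

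The populations were also compared at 20 °C, with unheated parents. CRE21731, on linkage group 1, stood at 32.1 ± 3.13 CPM in control-selected, 10.4 ± 4.98 in ancestor and 1.2 ± 1.09 in heat-selected larvae (SD, n = 6). It was −4.62 ± 0.45 (SE) on the log2 scale in heat-selected against control-selected larvae and −2.97 ± 0.45 against the ancestor. CRE24278 was at 20.4 ± 17 CPM in heat-selected, 0.117 ± 0.203 in ancestor and 0.401 ± 0.319 in control-selected larvae, a rise of 7.05 ± 0.81 and 5.51 ± 0.74 in heat-selected larvae. The rise of CRE24278 came from batch F alone, since the batch E libraries stood at 1.49 and 0 CPM. CRE10141 was higher in heat-selected larvae than in the ancestor, at 47.8 ± 40.2 against 4.3 ± 2.34 CPM (3.46 ± 0.56), again in batch F alone (8.46 and 0.867 CPM in batch E), and CRE_PX356_2650 was lower (−3.27 ± 0.75). In control-selected larvae CRE16136 and CRE15096 were higher than in the ancestor by 3.31 ± 0.56 and 2.09 ± 0.40 (CRE16136 at 2.9 and 1.88 CPM in batch C and 19.3 to 24.5 in batch D), and CRE_PX356_5841 and CRE_PX356_5228 lower (−3.48 ± 0.52 and −3.92 ± 0.92). The ancestor range of CRE_PX356_5228, 0.494 to 39.7 CPM, overlapped that of control-selected larvae, 0.188 to 2.14. For CRE_PX356_2650 the ancestor range of 1.67 to 20.7 CPM overlapped the heat-selected range of 0.366 to 1.74. CRE18318, at 35.1 ± 50.2 CPM, was 4.39 ± 0.93 higher in heat-selected than in control-selected larvae, and CRE16136 was lower (−2.89 ± 0.58).

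At 20 °C the test called 106 genes between heat-selected and ancestor larvae (68 higher, 38 lower in heat-selected), 30 between control-selected and ancestor larvae (13 and 17), and 83 between heat-selected and control-selected larvae (62 and 21). The majority direction of the last turned with 1 surrogate variable (161 higher, 260 lower), and that of the first with both batches weighted equally (329 and 370). Adjusted p-values were 5.5e-09 and 7.9e-05 for CRE21731 and 3.3e-07 and 2.1e-05 for CRE24278 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each population has its own 2 batches, so a population difference can be set only against the spread between 2 batches per population, and each selection regime is a single population. With counts summed per batch edgeR called 0 genes in each of the 3 comparisons (236, 179 and 94 at an unadjusted p under 0.05), while DESeq2 on single libraries called 194, 86 and 118 and limma-voom 75, 38 and 51. With batch as a random block, and 1 correlation shared by all genes, limma-voom called 6, 3 and 1 genes, CRE21731 among them for heat-selected against control-selected larvae (−5.18, adjusted p = 0.00092). Heat-selected libraries at 20 °C also held more reads outside genes (31.5% against 18.3% in the ancestor and 21% in control-selected larvae), and without the 4 libraries above 35% the counts were 43, 28 and 37. Summed in consecutive pairs, edgeR called 2, 0 and 1 (459, 290 and 281 unadjusted): CRE24278, CRE13477 (−2.30, adjusted p = 0.04) and CRE21731. CRE13477 lies outside the naming rule for this comparison and was chosen after its values were seen.

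At 30 °C the heat-selected and control-selected larvae differed in CRE01030, at 29.1 ± 22.2 against 0.861 ± 1.19 CPM (SD, n = 6; log2 difference 5.08 ± 0.85, SE), and in CRE_PX356_198, at 33.9 ± 35.9 against 1.41 ± 1.62 CPM (4.61 ± 0.67). CRE16931 and CRE29510 went the other way (−4.89 ± 0.87 and −4.69 ± 0.95): CRE16931 stood at 4.85 ± 5.09 CPM in heat-selected and 154 ± 231 in control-selected larvae, where replicates 5 and 6 gave 288 and 569. CRE16931 and CRE29510 were also higher in control-selected larvae than in the ancestor (5.1 ± 0.87 and 5.05 ± 0.96), and CRE_PX356_6120 and CRE01305 were lower (−2.93 ± 0.59 and −2.89 ± 0.77). CRE25992, on linkage group 4, was at 72.8 ± 36.6 CPM in heat-selected and 8.52 ± 6.41 in ancestor larvae (3.11 ± 0.44). CRE26230 was higher as well (2.83 ± 0.68), and CRE05523 and CRE_PX356_6121 were lower (−3.27 ± 0.78 and −3.21 ± 0.66).

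The counts at 30 °C were 152 for heat-selected against ancestor larvae (77 higher, 75 lower), 182 for control-selected against ancestor larvae (123 and 59) and 190 for heat-selected against control-selected larvae (93 and 97). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment CRE25992 had an adjusted p of 7.4e-05, CRE16931 of 0.0011 in both comparisons and CRE_PX356_198 of 4.4e-05. Scaled to total counts, the higher calls were 40 of 130, 116 of 147 and 47 of 170. Without ancestor replicates 5 and 6 at 30 °C, 85 genes were higher and 270 lower in heat-selected than ancestor larvae, and 112 higher and 238 lower in control-selected than ancestor larvae, so the majority direction of the latter turned. It also turned with both batches weighted equally (186 and 208) and with 1 surrogate variable (430 and 536). Batches are nested in populations here too. With batch as a random block limma-voom called 1, 1 and 0 genes (216 at an unadjusted p under 0.05 for the last), CRE25992 for heat-selected against ancestor larvae (3.00, adjusted p = 0.025) and, named after its value was seen, CRE17828 for control-selected against ancestor larvae (1.84, adjusted p = 0.0082). On counts summed per batch edgeR called 0 genes in all 3 (349, 354 and 289 at an unadjusted p under 0.05; DESeq2 on single libraries called 302, 286 and 261, limma-voom 104, 64 and 73). Summed in pairs, edgeR called 1, 0 and 0 (639, 577 and 516 unadjusted); the gene was CRE_PX356_452, 3.51 higher in heat-selected than ancestor larvae (adjusted p = 0.0048) and named after its value was seen.

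A population difference at 20 °C can be set against the heat response of the population that takes no part in it. Over all tested genes the heat-selected minus ancestor difference correlated with the control-selected response at r = 0.041 (jackknife SE 0.107; Spearman 0.061). The control-selected minus ancestor difference gave r = −0.079 (SE 0.1; Spearman −0.025) with the heat-selected response, and the heat-selected minus control-selected difference gave 0.174 (SE 0.232; Spearman 0.142) with the ancestor response. All 3 values lie within 1 SE of 0. Over the genes called for the population difference, a set chosen after the data were seen, r was 0.201 (SE 0.068, 106 genes), −0.263 (SE 0.141, 30 genes) and 0.5 (SE 0.13, 83 genes; Spearman 0.528; 75.9% with the same sign). These values are across genes, which are not independent replicates.

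The parental comparison asked whether larvae differed when their parents had lived at 30 °C, averaged over both larval temperatures. In the ancestor CRE03443, on linkage group 11, stood at 18.3 ± 2.37 CPM in larvae of heated parents (SD, n = 2) and 1.52 ± 0.735 in those of unheated parents (n = 6) at 20 °C. Its mean log2 change was 3.20 ± 0.36 (SE). CRE02924 went from 6.28 ± 2.04 to 52.8 ± 8.14 CPM at 20 °C and from 14.9 ± 10.8 to 74.6 ± 14.4 at 30 °C (3.15 ± 0.47). CRE_PX356_5212 and CRE_PX356_3558 had fitted changes of −4.32 ± 1.12 and −4.38 ± 1.16, but within batch A, which holds all heated-parent libraries, CRE_PX356_5212 stood at 0 and 0.783 CPM with unheated and 0.369 and 0.459 with heated parents at 20 °C. Both calls were lost without ancestor replicates 5 and 6 at 30 °C, labelled batch A, where CRE_PX356_5212 stood at 302 and 153 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 520 ancestor genes passed, 400 higher and 120 lower with heated parents, with adjusted p-values of 1.5e-07, 2.7e-05, 0.017 and 0.021 for these genes. Scaling to total counts gave 243 higher of 489, and a fit with no batch term 1020 higher and 1618 lower, so the majority direction depends on the scaling and on the batch term. Pairs summed leave 1 value per heated-parent group, so the spread of those groups is borrowed from the others and the fit does not test a parental effect against differences between cultures. With that limit 10 genes were called, all higher: CRE03443 and, named after their values were seen, CRE17923, CRE17924, CRE05020, CRE00131, CRE16785, CRE10143, CRE05605, CRE05809 and CRE_PX356_5025. Leaving out a library of heated parents moved the count to between 266 and 344 in 3 of the 4 cases, namely both replicates with larvae at 20 °C (266 and 289) and replicate 1 at 30 °C (344).

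In heat-selected larvae CRE30999 rose with heated parents from 5.54 ± 3.23 to 70.6 ± 13.8 CPM at 20 °C and from 1.58 ± 1.36 to 20.4 ± 7.4 CPM at 30 °C (SD, n = 6 and 2), a mean log2 change of 5.13 ± 0.49 (SE). CRE26693 had a fitted change of 5.59 ± 1.25 at low counts, with means of 1.17 ± 1.28 and 2.83 ± 2.79 CPM with unheated and heated parents at 20 °C and 4.39 ± 4.55 and 15.6 ± 3.61 at 30 °C. The fit sets the heated-parent libraries against batch E, where the unheated ones stood at 0 and 0 CPM at 20 °C and 0.618 and 0 at 30 °C; with no batch term the change was 1.56 (adjusted p = 0.394), and the call was lost without heated-parent replicate 1 at 20 °C (4.68, adjusted p = 0.184). The heat-induced genes CRE21296 and CRE26773 were lower (−4.42 ± 1.1 and −4.41 ± 1.06): at 30 °C CRE21296 stood at 0.734 ± 0.526 CPM with heated parents and 250 ± 122 with unheated parents, and CRE26773 at 0.442 ± 0.626 and 174 ± 92.8 CPM. The test called 746 genes, 373 higher and 373 lower, with adjusted p-values of 3.8e-09, 0.0046, 0.011 and 0.0083 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Scaling to total counts gave 484 higher of 727. With pairs summed, and the spread of the heated-parent groups again borrowed, 7 genes were called, all higher: CRE30999 and, named after their values were seen, CRE27885, CRE10841, CRE07335, CRE02474, CRE00669 and CRE09194. Without heated-parent replicate 1 or 2 of larvae at 20 °C the count was 329 or 396, and without unheated-parent replicate 1 or 2 of larvae at 30 °C 395 or 330.

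Control-selected larvae showed fewer parental calls. CRE27885 went from 2.89 ± 1.22 to 6.52 ± 0.64 CPM at 20 °C and from 0.933 ± 0.74 to 2.74 ± 0.304 at 30 °C (SD, n = 6 and 2), a mean log2 change of 2.66 ± 0.44 (SE), and CRE09194 rose by 2.34 ± 0.45. CRE27096 went from 64.3 ± 20.6 to 6.66 ± 3.45 CPM at 20 °C (−2.82 ± 0.54) and CRE10232 from 68.5 ± 22.1 to 7.87 ± 0.976 (−2.73 ± 0.55). Adjusted p-values were 0.0014, 0.0099, 0.0099 and 0.014 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which called 21 genes, 16 higher and 5 lower. The count was 2 without heated-parent replicate 1 at 20 °C, 6 and 11 without heated-parent replicates 1 and 2 at 30 °C, and 9 and 5 without unheated-parent replicates 1 and 2 at 20 °C. Summed in pairs, edgeR called 0 genes (313 at an unadjusted p under 0.05), while DESeq2 and limma-voom on single libraries called 51 and 24.

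Of the genes called for parental temperature in both the ancestor and the heat-selected population, which share no library, 105 of 122 moved in opposite directions (86.1%, exact binomial 95% interval 78.6 to 91.7, which treats genes as independent). Independent lists would share 28.8 genes. CRE30999 was among the 17 that moved alike. The heat-selected and control-selected populations shared 13 parental calls, all in the same direction, against 1.164 for independent lists. Without a batch term the share was 61.7% (exact interval 52.8 to 69.9; 133 shared genes, 92.5 for independent lists), and over 15 alternatives it ran from 61.7 to 92.2%. Over all tested genes the parental effects correlated at −0.13 between ancestor and heat-selected larvae, at −0.04 without ancestor replicates 5 and 6 at 30 °C and at 0.29 without a batch term, so the sign over all genes depends on the fit. Between heat-selected and control-selected larvae r was 0.33, and 0.48 without a batch term. With pairs summed no gene was called in both the ancestor and the heat-selected population by edgeR, so the share of opposite signs has no value there.

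**Figure D3:**
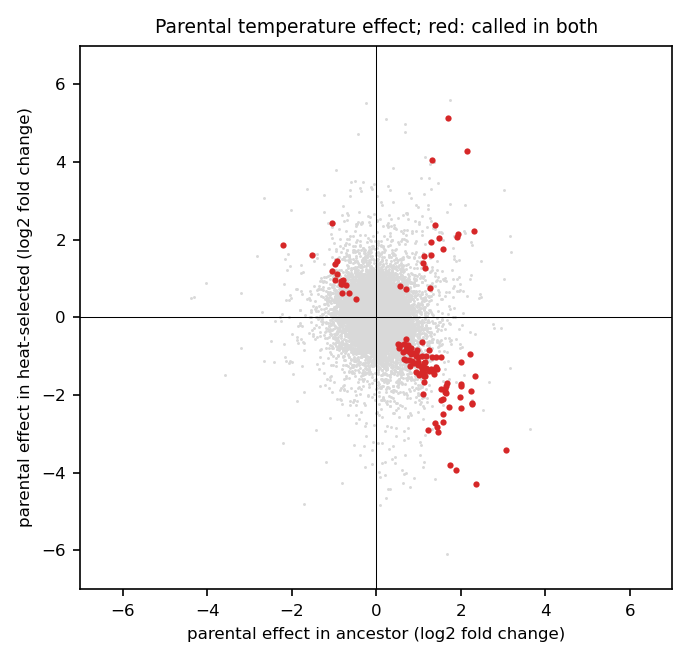
Change with heated parents (log2 fold change) of each tested gene in the ancestor and in the heat-selected population, with the 122 genes called in both in red. Of these genes 105 lie in the quadrants of opposite direction.

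The direct test of that difference gave CRE18121, on linkage group 9. In the ancestor at 20 °C it averaged 77.8 CPM (n = 2) with heated and 7.17 (n = 6) with unheated parents, and in heat-selected larvae 3.58 and 54.3 CPM. At 30 °C the ancestor means were alike, at 93.5 and 93.1 CPM, and those of heat-selected larvae were 3.33 and 136 CPM. Averaged over both larval temperatures, the difference of parental effects was −6.64 ± 0.70 (SE) on the log2 scale. At 20 °C CRE20636 stood at 343 ± 4.81 CPM (SD) with heated and 14.1 ± 5.87 with unheated parents in the ancestor. In heat-selected larvae the values were 11.9 ± 7.88 and 49.3 ± 31.2. At 30 °C they were 845 ± 82.8 and 260 ± 108 CPM in the ancestor and 14.6 ± 4.41 and 273 ± 206 in heat-selected larvae. The difference of parental effects on CRE20636 was −6.47 ± 0.73. CRE07335 differed the other way (5.15 ± 0.76), as did CRE_PX356_3558 (4.88 ± 1.59), whose call was lost without ancestor replicates 5 and 6 at 30 °C. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 1123 genes differed, 532 with a higher parental effect in heat-selected larvae and 591 lower, with adjusted p-values of 1.4e-08, 5e-08, 9e-06 and 0.046 for these genes. Scaling to total counts gave 801 higher of 1164. With pairs summed, under the same limit, 47 genes were called (8 higher, 39 lower), CRE18121, CRE20636 and CRE07335 among them. The parent-30 libraries of a population form 1 batch and 1 consecutive pair per group, so a heated-parent effect and the occasion of that culture cannot be told apart.

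Control-selected larvae differed from the ancestor in the parental effect on CRE02924 (−4.91 ± 0.78, SE) and CRE20636 (−4.60 ± 0.70): with heated parents at 20 °C CRE20636 stood at 9.03 ± 0.667 CPM in control-selected larvae (SD, n = 2) and 343 ± 4.81 in the ancestor. CRE_PX356_5228 and CRE18640 differed the other way (4.42 ± 1.14 and 3.09 ± 0.70), the call of CRE_PX356_5228 being lost with ancestor batches taken from the replicate number. In all, 152 genes differed (37 higher, 115 lower; 38 of 110 higher when scaled to total counts), with adjusted p-values of 0.00021, 9.3e-05, 0.041 and 0.015 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With pairs summed 1 gene was called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, CRE17924 (−3.71, adjusted p = 0.041), named after its value was seen. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 4 genes differed between heat-selected and control-selected larvae, each with a higher parental effect in heat-selected larvae in this fit: CRE30999 (4.52 ± 0.63, adjusted p = 0.0001), CRE28313 (3.22 ± 0.57, 0.0077) and, named after their values were seen, CRE19650 (1.92) and CRE09188 (1.60). Summed in pairs, edgeR called 0 of them (289 genes at an unadjusted p under 0.05), and DESeq2 and limma-voom called 32 and 3 genes on single libraries. Some fits with more calls gave both directions: 12 higher and 20 lower by DESeq2, 9 and 10 without a filter, 14 and 19 in batches A, C and E alone and 30 and 35 with 1 surrogate variable.

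Whether the response to 30 °C depended on the parents' temperature was tested within each population. In heat-selected larvae CRE03443 stood at 16.7 ± 1.53 CPM at 20 °C and 1.29 ± 1.31 at 30 °C with heated parents (SD, n = 2), and averaged 2.28 and 14.9 CPM with unheated parents (n = 6), a difference of log2 responses of −6.24 ± 0.79 (SE). Its neighbour CRE03457 differed by −4.91 ± 0.73, and CRE20697 and CRE03133 by 4.72 ± 0.86 and 4.12 ± 0.85. In the ancestor CRE28089 differed by 6.26 ± 0.96 and CRE18336 by 3.64 ± 0.68, and CRE04165 and CRE00862 by −4.84 ± 0.94 and −4.79 ± 1.02. The 2 ancestor libraries at 30 °C with heated parents lay far apart for the genes that rose. They stood at 2.89 and 22.1 CPM for CRE28089 and at 8.29 and 72.8 for CRE18336. In control-selected larvae CRE02924 and CRE18121 differed by −4.91 ± 1.06 and −4.55 ± 0.99, and CRE15096 and CRE02474 by 2.67 ± 0.60 and 2.33 ± 0.43. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 215 genes passed in the ancestor (141 higher, 74 lower; 81 of 171 higher when scaled to total counts), 24 in control-selected (5 and 19; 2 of 21 higher with DESeq2's size factors) and 73 in heat-selected larvae (41 and 32; 45 and 85 without a filter, 24 and 89 in batches A, C and E alone, 117 and 206 with 1 surrogate variable), with adjusted p-values from 8.4e-06 for CRE03443 to 0.047 for CRE15096 among the genes named. With pairs summed edgeR called 0 genes in each population (665, 297 and 537 at an unadjusted p under 0.05). On single libraries DESeq2 called 430, 74 and 167 and limma-voom 314, 16 and 68. In the ancestor the count was 2 without replicate 1 and 483 without replicate 2 of the heated-parent larvae at 30 °C, and 11 and 64 without replicates 1 and 2 of those at 20 °C. At 30 °C replicate 1 held 41.1% of reads outside genes and replicate 2 9.73%. In control-selected larvae edgeR called 0 genes without any of 3 of the 4 heated-parent libraries (replicate 2 at 20 °C and both at 30 °C; 557, 816 and 566 genes at an unadjusted p under 0.05) and 3 without replicate 1 at 20 °C. In heat-selected larvae the count was 12 and 156 without heated-parent replicates 2 and 1 at 30 °C, and 20 without either at 20 °C.

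**Figure D4:**
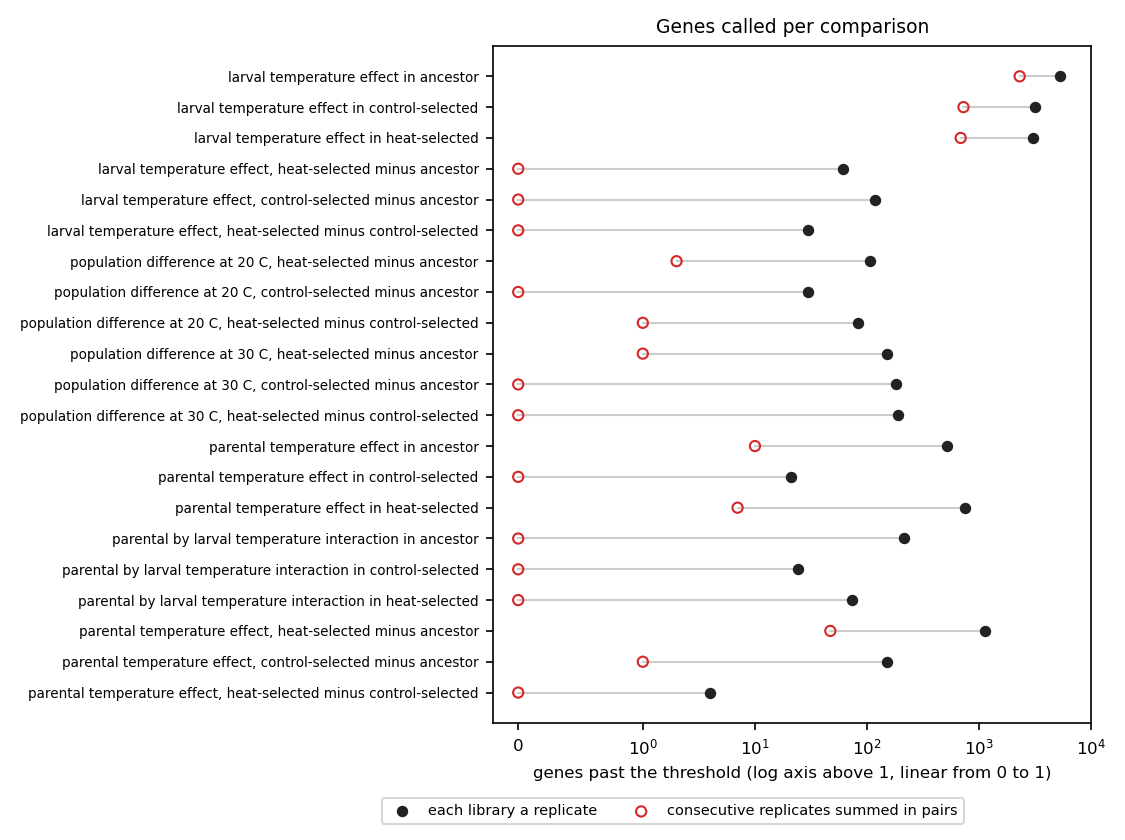
Number of genes past the threshold (log axis above 1) in each of the 21 comparisons, with each library as a replicate (filled) and with consecutive replicates summed in pairs (open). With pairs summed the larval responses give 2293, 723 and 683 genes, and the difference of parental effects between heat-selected larvae and the ancestor gives 47, with 1 value per heated-parent group.

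Set against the response to 30 °C of a population that shares no library, parental effects in the ancestor correlated over the 520 called genes at r = 0.301 (jackknife SE 0.065; Spearman 0.364) with the control-selected and 0.204 (SE 0.077; Spearman 0.199) with the heat-selected response. Parental effects in heat-selected larvae correlated over their 746 called genes at −0.436 (SE 0.1; Spearman −0.375) with the ancestor and −0.302 (SE 0.104; Spearman −0.297) with the control-selected response. These sets of called genes were chosen as a test after the data were seen, and the values are across genes. Over all 13460 tested genes the planned correlations were 0.146 (SE 0.083) and 0.07 (SE 0.089) for the ancestor and −0.117 (SE 0.192) and −0.058 (SE 0.095) for heat-selected larvae, each within 2 SE of 0. For control-selected larvae they were −0.044 (SE 0.265) with the ancestor and −0.058 (SE 0.162) with the heat-selected response.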

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

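All tests of explanations in this part were chosen after the results were seen; the comparisons and the regroupings of libraries, whose numbers include the real grouping, were planned. The regroupings refit only the libraries compared, so their limma-voom counts differ from those of the fit of all 48 libraries. Of 214 groups of 6 libraries examined for a library far from the others, 7 had such a library (3.27%), and chance gives about 1 in 20.

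The effect of larval temperature differed between populations for 61 genes (heat-selected against ancestor), 117 genes (control-selected against ancestor) and 30 genes (heat-selected against control-selected) by a test of the difference itself. Single libraries were regrouped as if independent. In the real grouping limma-voom called 31, 42 and 24 genes, with 2, 5 and 2 of 100 groupings as large. The highest other groupings called 72, 3058 and 968 genes. The regroupings kept the real batches, beside which only the shuffled fits could hold a population term. The counts are therefore not like for like, the shares are not adjusted over the comparisons, and chance was excluded for none of the 3. With consecutive replicates summed in pairs edgeR called 0 genes in each of the 3 (403, 780 and 347 at an unadjusted p under 0.05). On single libraries DESeq2 called 106, 294 and 79, and limma-voom 71, 118 and 27 in the fit of all 48. Groupings that called 968 or 3058 genes point to a structure of the samples.

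The interaction of parental and larval temperature was called for 215 genes in the ancestor (2 to 483 with 1 library left out), 24 in the control-selected and 73 in the heat-selected population, and by edgeR for 0 genes in each with pairs of replicates summed (665, 297 and 537 at an unadjusted p under 0.05; DESeq2 on single libraries 430, 74 and 167, limma-voom 314, 16 and 68). Parental effects differed between heat-selected and ancestor larvae for 1123 genes, between control-selected and ancestor larvae for 152 and between heat-selected and control-selected larvae for 4, namely CRE30999, CRE28313, CRE09188 and CRE19650. With pairs summed the counts were 47, 1 and 0 (the last by edgeR with 289 at an unadjusted p under 0.05; DESeq2 32 and limma-voom 3 on single libraries). CRE09188 and CRE19650 fall outside the naming rule and were chosen after their values were seen.

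Reads outside genes, which no comparison uses, made up 31.5 ± 6.57% (SD, n = 6) of heat-selected and 18.3 ± 3.82% of ancestor libraries at 20 °C with unheated parents, a difference of 13.2 points (exact permutation p = 0.0022, adjusted over 6 comparisons 0.013). Control-selected libraries stood at 21 ± 3.63%, 10.5 points below the heat-selected ones (exact p = 0.0043, adjusted 0.013). At 30 °C the heat-selected libraries were 7.56 points above the ancestor (exact permutation p = 0.024, adjusted 0.048). They were 2.79 points above the control-selected ones (exact permutation p = 0.29, adjusted 0.29). These tests permute single libraries as if independent, so they do not set a population difference against the spread between batches. Heat-selected libraries at 20 °C stood at 24 and 27.4% in batch E and at 26.7 to 40% in batch F.

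Control-selected replicate 3 at 20 °C with unheated parents had 3139181 counts in genes, and the others of its group 4365956 to 4992740. CRE13477 stood at 33.5 CPM in ancestor replicate 2 at 20 °C, and at 48.5 to 59.7 in the others. Heat-selected replicate 3 at 20 °C held 1.46 CPM of CRE_PX356_198 (0 in the others) and 26.4 CPM of CRE21296 (0 to 1.06 in the others). CRE26693 was at 0.39 CPM in ancestor replicate 5 at 20 °C (3.05 to 5.64 in the others). CRE15096 was at 1.51 CPM in control-selected replicate 3 at 30 °C (2.55 to 3.2), and CRE18640 at 0.267 CPM in control-selected replicate 1 at 30 °C (1.85 to 3.82).

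Among genes called for parental temperature in both the ancestor and the heat-selected population, 86.1% moved in opposite directions. Over 15 alternatives the share ran from 61.7% (no batch term) to 92.2%. It was 75.2% with 1 surrogate variable that takes up the composition axis of the libraries, 83.6% without the 4 libraries richest in reads outside genes and 80.3% with ancestor batches taken from the replicate number, which argues against each of these as the whole cause. The heated-parent libraries of a population come from 1 batch and, per group, 1 pair of replicates. A single culture occasion of heated parents therefore cannot be told apart from an effect of parental temperature that differs between populations. Such an effect stays open and untested, and the design does not part an inherited one from exposure of the embryos before bleaching. Regrouping did not exclude chance for the parental calls of the ancestor (273 genes by limma-voom, 7 of 90 groupings as large, highest other 4115, which points to a structure of the samples); the 18 distinct groupings in each derived population are too few for a share under 0.05 (control-selected 40 genes, 3 as large, highest other 83; heat-selected 455 genes, 1 as large, highest other 86).

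The ancestor had 1.67 times as many larval temperature calls as the control-selected population, but not in every fit set in advance: ancestor and control-selected counts were 4218 and 3920 in fits within the population, 3271 and 3460 with a replicate block, 2893 and 357 in batches A and C and 2958 and 3250 in batches B and D. Depth alone is argued against, since the ratio was 1.97 with all libraries thinned to the lowest total. The ratio was 1.05 with 1 surrogate variable and 1.15 without ancestor replicates 5 and 6 at 30 °C, so the library composition axis and these libraries may each account for the excess, and a stronger response of the ancestor was not tested apart from them. The larval effects themselves exceeded all other groupings: 3786 genes by limma-voom in the ancestor (1 of 100, highest other 3251), 3791 in the control-selected (1 of 100, highest other 27) and 2811 in the heat-selected population (1 of 100, highest other 6). The ancestor grouping with 3251 genes set replicates 1, 2, 5 and 6 at 20 °C with replicates 1 and 2 at 30 °C.

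The population differences rest on 2 batches per population. With a batch counted as 1 replicate edgeR called 0 genes over the 6 comparisons (94 to 354 at an unadjusted p under 0.05 in each; DESeq2 and limma-voom on single libraries called 86 to 302 and 38 to 104), while batch as a random block in limma-voom, with 1 correlation shared by all genes, left 6, 3 and 1 genes at 20 °C and 1, 1 and 0 at 30 °C (216 unadjusted for the last), so batch differences stay open for most of the called genes. Regrouping treats single libraries as independent, while pairs summed left 2, 0 and 1 genes at 20 °C and 1, 0 and 0 at 30 °C. The shares below are also not adjusted over the comparisons, so they do not exclude chance. At 20 °C the real grouping was among the largest (18 genes by limma-voom, 2 of 100 as large, highest other 1778 for heat-selected against ancestor; 16, 4 of 100, 5490 for control-selected against ancestor; 41, 2 of 100, 2707 for heat-selected against control-selected), and so it was at 30 °C (8 genes, 4 of 100, 2301; 2 genes, 1 of 100, 0; 6 genes, 3 of 100, 2682, in the same order). Groupings that call 1778 to 5490 genes point to a structure of the samples, and selection, drift and batch all stay open.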

How the results depend on the processing

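Tests chosen after the results were seen are the surrogate variable, the ancestor batches from the replicate number, the omissions of 4 and of 2 libraries, thinning, correlations over the genes called for the population difference or the parental effect, and pairs of replicates; the others were planned. Counts are genes called, in the order ancestor, control-selected, heat-selected, or heat-selected minus ancestor, control-selected minus ancestor, heat-selected minus control-selected. Planned set tests (camera, fry) were not run, lacking gene names. Named genes were picked for large changes, so direction was hardly tested. Leave-one-out refits included, 2239 values kept the call, 425 lost it, none reversed. Counts summed per batch lost 24 of 24, batch as a random block 22 of 24. Except where a setting uses fewer libraries or genes, the cause was not tested.

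With consecutive replicates summed in pairs (edgeR), 18 of 82 named calls stayed. Larval effects gave 2293, 723 and 683, their differences 0, 0 and 0 (403, 780 and 347 at an unadjusted p under 0.05; DESeq2 on single libraries 106, 294 and 79, limma-voom 71, 118 and 27), and population differences 2, 0 and 1 at 20 °C and 1, 0 and 0 at 30 °C. Parental effects gave 10, 0 and 7, interactions of parental and larval temperature 0, 0 and 0 (665, 297 and 537 unadjusted), and differences of parental effects 47, 1 and 0. Fewer replicates are part of this construction.

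Other settings of scaling and filtering moved fewer counts. At an absolute log2 change of at least 1, larval effects gave 2623, 1281 and 1201 and parental effects in ancestor and heat-selected larvae 307 and 488, by construction. DESeq2's size factors moved the parental difference between the derived populations to 2. Total counts moved the larval difference between the derived populations to 51 and the control-selected interaction to 41. They shifted the median gene by −0.29 and −0.18 in the larval effects of ancestor and heat-selected larvae, by 0.12, 0.32 and −0.21 in the larval differences, by −0.12 and −0.15 at 20 °C and −0.16 and −0.2 at 30 °C in population differences, by 0.12, −0.14 and 0.38 in the interactions and by 0.11 in the last parental difference. Without a filter the counts were 262 and 53 for the larval differences control-selected minus ancestor and heat-selected minus control-selected, 97 for heat-selected minus ancestor at 30 °C, 40 for the control-selected parental effect, 42 and 130 for the control-selected and heat-selected interactions and 19 for the last parental difference. A minimum count of 50 gave 19 for control-selected minus ancestor at 20 °C.

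DESeq2 called 106, 294 and 79 genes in the larval differences, 194 and 86 in the first 2 population differences at 20 °C, 302 and 286 at 30 °C, 786 and 51 in the parental effects of ancestor and control-selected larvae, 430, 74 and 167 in the interactions, and 251 and 32 in the last 2 parental differences. limma-voom called 51 for heat-selected minus control-selected at 20 °C, and 64 and 73 for the last 2 differences at 30 °C.

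Without a batch term the larval effects gave 2977, 2058 and 1937, their differences 10, 1 and 7, parental effects 2638, 132 and 472, interactions 31, 1 and 16, and parental differences 555, 333 and 8. A fit within the population gave parental effects of 256, 40 and 444 and interactions of 45 and 60 in ancestor and control-selected larvae. Batches A, C and E alone gave larval effects of 2893, 357 and 759, interactions of 49, 7 and 113 and 33 for the last parental difference; batch B alone gave 2958 for the ancestor's larval effect. A replicate block gave 3271 for the ancestor's larval effect, 9 and 14 for the first 2 larval differences and 111 for the ancestor's interaction. Replicate numbers did not pair libraries across groups: of 18 pairs of libraries with the same number at 20 and 30 °C, r ran from −0.68 to 0.67, 3 exceeded 0.1 and 1 had its best partner under the same number.

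For population differences, batch as a random block (limma-voom) gave 6, 3 and 1 at 20 °C and 1, 1 and 0 at 30 °C (216 unadjusted for the 0; edgeR 190 and DESeq2 261 on single libraries). Both batches weighted equally gave 699 and 475 for the first 2 at 20 °C and 525, 394 and 339 at 30 °C. Counts summed per batch gave 0, 0 and 0 at each temperature by edgeR (236, 179 and 94 unadjusted at 20 °C, 349, 354 and 289 at 30 °C; DESeq2 86 to 302 on single libraries).

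With 1 surrogate variable the larval effects of control-selected and heat-selected larvae gave 4763 and 4508, the last 2 larval differences 246 and 276, population differences 387, 188 and 421 at 20 °C and 952, 966 and 714 at 30 °C, parental effects 1379, 106 and 1821, interactions 632, 159 and 323 and parental differences 2079, 434 and 65. Ancestor batches from the replicate number gave larval differences of 31, 48 and 54, a heat-selected interaction of 119 and 17 for the last parental difference, and 7 of 58 named calls were lost: CRE23514, CRE24133 and CRE_PX356_6307 in larval differences, CRE_PX356_5212 and CRE_PX356_3558 in the ancestor's parental effect, and CRE_PX356_3558 and CRE_PX356_5228 in parental differences. Without the 4 libraries richest in reads outside genes, larval differences heat-selected minus ancestor and heat-selected minus control-selected gave 33 and 7, the same population differences at 20 °C 43 and 37, parental effects in ancestor and heat-selected larvae 312 and 369, interactions 2, 11 and 12 and parental differences 550, 72 and 2. Without ancestor replicates 5 and 6 at 30 °C, the first 2 population differences at 30 °C gave 355 and 350, the control-selected parental effect 33, the heat-selected interaction 124 and the last parental difference 16.

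The majority direction of a comparison turned in these settings, given as higher and lower counts. Larval effects: ancestor, total counts 1701 and 3373, fit within the population 2096 and 2122; control-selected, no filter 1295 and 1471, minimum count 50 1357 and 1402, limma-voom 1630 and 1673, fit within the population 1943 and 1977, batches A, C and E alone 132 and 225, surrogate variable 2359 and 2404, pairs summed 347 and 376; heat-selected, no filter 1302 and 1265, batches B, D and F alone 1128 and 1107, surrogate variable 2417 and 2091. Larval differences: control-selected minus ancestor (58 and 59), DESeq2's size factors 68 and 58, total counts 90 and 52, minimum count 50 60 and 58, no batch term 1 and 0, replicate block 12 and 2, ancestor batches from the replicate number 44 and 4, thinned 21 and 19; heat-selected minus control-selected, surrogate variable 166 and 110. Population differences at 20 °C: heat-selected minus ancestor, batches weighted equally 329 and 370; control-selected minus ancestor, minimum count 50 10 and 9, limma-voom 23 and 15, random block 2 and 1, surrogate variable 108 and 80; heat-selected minus control-selected, surrogate variable 161 and 260, random block and pairs summed 0 and 1. At 30 °C: heat-selected minus ancestor (77 and 75), total counts 40 and 90, batches weighted equally 242 and 283, surrogate variable 475 and 477, without ancestor replicates 5 and 6 85 and 270; control-selected minus ancestor, batches weighted equally 186 and 208, surrogate variable 430 and 536, without ancestor replicates 5 and 6 112 and 238; heat-selected minus control-selected (93 and 97), minimum count 50 93 and 84, DESeq2 140 and 121, limma-voom 52 and 21, batches weighted equally 200 and 139, surrogate variable 401 and 313, thinned 41 and 35.

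Parental effects turned in the ancestor with total counts (243 and 246) and no batch term (1020 and 1618). Interactions turned in the ancestor with total counts (81 and 90) and no filter (126 and 130), in control-selected larvae with the surrogate variable (81 and 78), and in heat-selected larvae with no filter (45 and 85), no batch term (7 and 9), the fit within the population (23 and 26), batches A, C and E alone (24 and 89), the replicate block (37 and 39), the surrogate variable (117 and 206), ancestor batches from the replicate number (55 and 64), either omission (5 and 7 without 4 libraries, 56 and 68 without 2) and thinning (16 and 18). Parental differences turned for heat-selected minus ancestor with total counts (801 and 363) and no filter (495 and 494), and for heat-selected minus control-selected with DESeq2 (12 and 20), no filter (9 and 10), batches A, C and E alone (14 and 19) and the surrogate variable (30 and 35).

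Depth limits the counts. Thinned to the lowest total, larval effects gave 3002, 1524 and 1525, their differences 18, 40 and 6, population differences 41, 3 and 46 at 20 °C and 38, 51 and 76 at 30 °C, parental effects 267, 5 and 276, control-selected and heat-selected interactions 4 and 34 and parental differences 512, 75 and 2.

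Correlations over sets of called genes, chosen by their own fits, moved from those over all genes: 0.858, 0.869 and 0.817 for larval effects of heat-selected and ancestor, control-selected and ancestor, and heat-selected and control-selected larvae; 0.201, −0.263 and 0.5 for population differences at 20 °C against the response of the third population. For parental effects they were 0.301 and 0.204 in the ancestor, −0.33 in control-selected larvae against the ancestor response, and −0.436 and −0.302 in heat-selected larvae.

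Leaving out single libraries, larval effects ranged from 4023 to 5622, 2677 to 3156 and 2327 to 2999, with no library moving one by over 1.5 times. In what follows p20 and p30 are parents at 20 and 30 °C, l20 and l30 larvae, and r the replicate; libraries that move a count by over 1.5 times are in brackets with the count without them. Larval differences, with p20 throughout: 36 to 79 (ancestor l30 r3 36); 59 to 244 (control-selected l20 r4 59, r6 64, l30 r6 60, r5 64, r3 214, r4 244; ancestor l20 r1 62, r2 67, r6 204, l30 r3 73, r1 198, r2 213); 14 to 49 (heat-selected l30 r4 14, r3 16, r5 46; control-selected l30 r5 17, r6 17, r4 49). Population differences at 20 °C: 65 to 184 (heat-selected r6 65, r5 67, r3 70, r1 184); 14 to 52 (ancestor r1 14, r2 17, r4 49, r6 52; control-selected r1 15, r2 18); 49 to 116 (heat-selected r3 49, r5 54). At 30 °C: 53 to 225 (heat-selected r2 53, r1 58, r3 82, r4 88); 59 to 230 (control-selected r6 59, r5 81); 83 to 275 (control-selected r6 83, r5 115; heat-selected r2 116).

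A heated-parent group left with 1 library is assumed to vary like the other groups. Parental effects: 266 to 710 (p30 l20 r1 266, r2 289, p30 l30 r1 344); 2 to 22 (p30 l20 r1 2, p20 l20 r2 5, r1 9, p30 l30 r1 6, r2 11); 329 to 1006 (p30 l20 r1 329, r2 396, p20 l30 r2 330, r1 395). Interactions: 2 to 483 (p30 l30 r1 2, r2 483, p30 l20 r1 11, r2 64); 0 to 38 (p30 l20 r2 0, p30 l30 r1 0, r2 0, by edgeR with 557, 816 and 566 unadjusted, DESeq2 74 and limma-voom 16 on all libraries; p30 l20 r1 3, p20 l20 r3 11, r4 11, r5 12, r6 13, r1 38, p20 l30 r5 12); 12 to 156 (p30 l30 r2 12, r1 156, p30 l20 r1 20, r2 20, p20 l30 r6 114). Parental differences: 681 to 1616 (ancestor p30 l20 r1 681, heat-selected p20 l30 r2 685, r1 715); 83 to 168 (control-selected p30 l20 r1 83, r2 97, p20 l20 r2 84, p30 l30 r2 90, r1 93; ancestor p30 l20 r2 85, r1 90, p30 l30 r1 89); 1 to 19 (20 of 32 libraries: 1 without heat-selected p20 l30 r1 or control-selected p30 l30 r1; 2 without control-selected p20 l20 r3 to r6, p20 l30 r2 or r6, p30 l20 r1 or p30 l30 r2, or heat-selected p20 l20 r4 or r6, p20 l30 r2, p30 l20 r1 or r2 or p30 l30 r2; heat-selected p20 l20 r2 7, r1 19, p30 l30 r1 17, control-selected p20 l20 r1 12).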

Other observations

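All tests in this part were chosen after the results were seen, apart from the correlations over all genes.

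Replicates of a group resembled each other in consecutive pairs. Among the 15 ways to pair 6 replicates, the consecutive 1 gave the smallest distance in 4 of the 6 groups with unheated parents, where chance gives 6.67% per group. The root mean square log2 difference was 0.462 for consecutive pairs and 0.612 for the next best pairing in the ancestor at 30 °C, 0.604 and 0.73 in the control-selected and 0.581 and 0.761 in the heat-selected population. At 20 °C it was 0.768 and 0.788 in the heat-selected population, while another pairing was closer in the ancestor (0.501 against 0.606) and in the control-selected population (0.552 against 0.555). The value of 4 groups may mean that consecutive replicates share a source such as a culture or a preparation, but batch labels also part replicates 1 and 2 from the others in most groups, and the labels do not settle it.

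Ancestor replicates 5 and 6 at 30 °C carry the label of batch A. Over 4706 genes that differ between batches A and B at 20 °C, 87.4 and 88.7% stood nearer to batch B in these libraries, against 3.91 and 2.87% in replicates 1 and 2 (batch A) and 95.5 and 92.4% in replicates 3 and 4 (batch B). A wrong batch label of ancestor 30 °C replicates 5 and 6 is a candidate explanation, and the genes are not independent replicates.

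Parental calls of the ancestor shared the direction of the larval response in 65.8% of genes for the control-selected response (exact binomial 95% interval 61.5 to 69.8) and 60% for the heat-selected response (55.6 to 64.2). For parental calls of the heat-selected population the shares were 33.6% (30.3 to 37.2) with the ancestor and 35.8% (32.3 to 39.3) with the control-selected response. Over the alternatives they ranged from 50.2 to 72.7, 40 to 67.4, 18.9 to 35.4 and 25.6 to 57.1%. For the 21 parental calls of the control-selected population the share was 28.6% with the ancestor and 28.6% with the heat-selected response. Over the alternatives these ran from 20.5 to 40 and from 11.1 to 30%. A hypothesis in line with the first values is that larvae of heated ancestor parents resemble heated larvae in part; the heat-selected values argue against it there. The intervals treat genes as independent.

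The heat-induced gene CRE18322 may show the same contrast between ancestor and heat-selected larvae. CRE18322 stood at 141 ± 51.3 CPM (SD, n = 2) in control-selected and 92.4 ± 47.3 in heat-selected larvae at 30 °C with heated parents, and at 7390 ± 3430 in the ancestor. With unheated parents the means were 3840 ± 4250, 10500 ± 7180 and 7050 ± 2950 (n = 6), but control-selected replicates 1 and 2, the pair of batch C, stood at 313 and 470 CPM. Averaged over both larval temperatures, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called the parental effect on CRE18322, a gene chosen here after its values were seen, in heat-selected larvae (log2 change −3.749, adjusted p = 0.0114) and its difference from the ancestor (−4.185, adjusted p = 0.0185), but not the effect in control-selected larvae (−1.293, adjusted p = 0.98) or an interaction with larval temperature in any population (adjusted p = 0.728, 0.206 and 0.109). These calls were not tried under the alternatives and rest on 1 culture occasion of heated parents.

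Calls lay in blocks of neighbouring gene models more often than in 10000 shuffles over 1514 blocks. Pairs of calls of like direction in a block exceeded the shuffled mean 2.16 times for the parental effect in the ancestor and 1.52 times in the heat-selected population, and 1.2, 1.29 and 1.3 times for the larval effect in the ancestor, control-selected and heat-selected populations (permutation p = 1e-04, the smallest they can give, adjusted 0.00017). The control-selected parental effect gave 0 pairs against 0.135 shuffled, with too few calls to tell. Population differences clustered too, at 2.46, 8.26 and 4.85 times the shuffled mean at 20 °C and 3.2, 2.89 and 2.57 times at 30 °C. The order is heat-selected minus ancestor, control-selected minus ancestor and heat-selected minus control-selected. These ratios rest on 2 to 29 pairs, with permutation p-values from 1e-04 to 0.025, or 0.00017 to 0.027 adjusted over all comparisons tested for blocks. On linkage group 9, 9 of 19 tested genes of a block rose with heated parents in the ancestor, CRE17923 and CRE17924 among them (median log2 change 1.72 over the 9 and 1.39 over all 19, adjusted p = 2.2e-06). On scaffold 41, 16 of 27 genes of a block fell at 30 °C in the ancestor, 13 in the heat-selected and 11 in the control-selected population (adjusted p = 0.0033 and 0.005 for the first 2; medians over all 27 of −0.91, −0.58 and −0.88). On scaffold 209, CRE18322, CRE18318 and CRE15096 were among 7 of 23 genes lower with heated parents in heat-selected larvae (median −1.67 over the 7, adjusted p = 0.0036), but the median over all 23 was −0.04 and 1 gene rose. Shared regulation, tandem copies that share reads and overlapping models could each give such blocks, and the tests do not part them. Reads aligned more than once and reads on overlapping models were not counted, which limits the part that shared reads can play.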
